A study of Mus musculus with 904 samples.

How the data were processed

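The series holds RNA libraries of 904 single nuclei, amplified with SMART-Seq v4 and made into sequencing libraries with Nextera XT, per the labels' protocols. The deposited values are counts of reads per gene in 1 table of 32285 genes and 2501 columns; reads were aligned with STAR 2.7.2a to mm10, per the submitters' processing notes, and the counting step is not described in the sources used here. The 904 columns that match a sample of the series were used, and the other 1597 columns, which no label of the series describes, were not. Gene IDs were matched to symbols and coordinates in GENCODE M21 (32158 matched, 127 not, 52 sharing a symbol with another ID). All rows used are mouse genes, so the level of the transgene was not analysed here. Empty wells and doublets were not called, since the protocol sorts 1 nucleus per well.

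Nuclei were kept with at least 1000 genes detected and at least 10000 reads assigned to genes. Counts were scaled to 10000 per nucleus and log transformed, and the 2000 most variable genes, with held-out and mitochondrially encoded genes excluded, were scaled (values capped at 10) and reduced to 30 principal components. A graph of 15 nearest neighbours was clustered with the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, figures with matplotlib 3.10.9). The marker lists were fixed before the data were examined. How many markers a name requires was set after the data were seen: at least 3 markers detected in 25% of a cluster's nuclei at 2 times the level of the other nuclei (10 CPM, reads scaled to a sum of 1e6, added to both), with at least 1 among the 10 leading genes and no other class with more there. A name therefore ends in -like. GABAergic-like is the sum of the named interneuron clusters. The 281 held-out genes are ion channels, neurotransmitter receptors and cadherins, which took no part in clustering. They are the only genes whose tests between classes are reported. Levels of some other genes are given without a test for a large unnamed cluster.

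Nuclei were grouped by the construct in the sample title and summed per construct, and per construct and pool or class where those were compared. One planned grouping of the nuclei and some genes that the naming rule selects are not reported here. Each class and pool comparison used constructs with at least 5 nuclei on both sides and needed 4 such constructs; the suffix BC needed 8 nuclei per construct. Summed counts were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with the element, position, pair or construct as a block, and adjusted by Benjamini-Hochberg at 0.05 over all genes tested, between classes as well. The SE of a log2 fold change is its size divided by the square root of F. Fold changes against a side with 0 reads are lower bounds that set that side to 3 counts, and those with 1 to 3 reads are ratios with exact counting intervals. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. Class shares and depth by element position were tested by exact paired permutation over 64 sign patterns. Shares carry Clopper-Pearson and single-construct levels Poisson 95% intervals. Single constructs were compared over genes with at least 20 CPM and reads in 25% of nuclei in at least 1 of them, without a test.

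The lists were GABAergic identity, glutamatergic identity, glia and vascular cells, immediate early genes, heat shock and unfolded protein response, interferon and antiviral response, DNA damage and p53 targets, H2B histone genes, other histone genes, Sm proteins and histone mRNA processing, hnRNP genes, nuclear long noncoding RNAs, mitochondrially encoded transcripts and ribosomal protein genes. Between classes they were potassium channels, calcium channels, sodium and HCN channels, GABA receptors, glutamate receptors, monoamine, acetylcholine and opioid receptors, and cadherins and protocadherins. Named genes followed a rule set before the data were examined: the 10 largest fold changes in each direction among called genes, or the 3 smallest p in each direction where fewer than 10 were called, the 2 members of each list with the smallest p, the 5 largest ratios in each direction between single constructs, and a fixed set of markers.

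Read depth and the number of nuclei set the precision. The kept nuclei hold 30023 to 719419 reads. Among 835 nuclei an exact interval on the GABAergic-like share, which takes nuclei as independent, runs from 29.8% to 36.2%. Each fit was tested on counts simulated around a single mean per gene over the summed libraries, with 200 genes changed. Genes were drawn independently, without differences between elements, constructs or pools. The real libraries differ in cell makeup, so the shares and false calls below may not hold for them. With a true log2 change of 4, edgeR called 47.3% of the changed genes that passed the filter for element position (16388 genes run), 55.9% for family (14983), 61.1% for copy number (15346), 24.7% for the suffix BC (12932), 49.0% for pool S40325 (15889), 51.1% for pool S40317 (14808), 22.9% between Pvalb-like and Sst-like (12120), 49% between GABAergic-like and glutamatergic-like nuclei (14855) and 45.9% for the large unnamed cluster (14964). With a change of 2 these shares were 19.8%, 25.8%, 19.4%, 0, 7.14%, 8.25%, 1.05%, 31.6% and 10.2%. Unchanged genes called were 13, 3, 18, 1, 4, 12, 1, 4 and 1 in the same order, which for element position, copy number and pools S40325 and S40317 is above the 5% of calls aimed at.

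Alternatives set before the data were examined were RLE factors in edgeR, DESeq2 1.42.0, no low-count filter, no nucleus filter, at least 2000 genes per nucleus, the mean of log2(CPM + 1) over nuclei in limma, no block, pool as a term, GABAergic-like nuclei only, resolutions 0.5 and 2, at least 10 nuclei per sum, each construct, element or pair left out and, for shares, each library pool left out. Vip-like against Lamp5-like nuclei and interneurons of medial against caudal origin were planned and could not be run, since no Vip-like cluster was found and fewer than 4 constructs had enough nuclei.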

Results

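Nuclei were sorted for fluorescence from mouse brain 3 to 4 weeks after delivery of adeno-associated virus in which the DLX2.0 enhancer, which targets GABAergic neurons of the forebrain, drives a nuclear reporter. RNA of single nuclei was amplified by SMART-Seq, which reads whole transcripts and gives each nucleus its own library without molecular identifiers. The labels place all 904 nuclei in primary visual cortex. Most reporters join SYFP2, a yellow fluorescent protein, to the histone H2B, which carries it into the nucleus. Around this fusion the constructs place RNA elements: BORG, a motif of a nuclear-retained noncoding RNA, SIRLOIN, a nuclear localization element derived from short interspersed repeats, or smOPT and U7snRNAOPT, which carry an optimised site for the Sm proteins that assemble on small nuclear RNAs. The title of the series concerns technical and biological noise in multiplexed enhancer screens, and the comparisons ask whether the form of the reporter or the handling of the libraries moves the cells and transcripts that are recovered.

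Sample titles name 16 constructs, 12 with 48 nuclei, 3 with 96 and 1 with 40. Of these, 12 carry 1 of 6 elements either before or after SYFP2-H2B, and the remaining 4 are dTomato-H2B, SYFP2-10aa-H2Bmod, SYFP2-P2A-3XFLAG-H2B and the same P2A construct followed by SIRLOIN. Every result by construct rests on the titles alone, and how well they assign nuclei to constructs is uncertain. The descriptions further place the nuclei in 3 library pools of 107 (pool S40317), 407 (pool S40325) and 390 (pool S40327) nuclei. No label names an animal. Nuclei of 1 construct were therefore treated as 1 sample, and the p-values measure only the spread between these samples, which may be technical.

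The filter kept 835 nuclei with 30023 to 719419 reads assigned to genes, a median of 260274, and a median of 2789 genes detected. Summed over nuclei, the constructs hold between 9505168 reads (3xU7snRNAOPT-SYFP2-H2B) and 26959589 reads (SYFP2-P2A-3XFLAG-H2B-SIRLOIN). Of the 69 nuclei left out, 40 belong to pool S40325, 28 to pool S40327 and 1 to pool S40317. No 2 libraries had identical counts, and the highest correlation between any pair of nuclei was 0.667. The transgene was not analysed here, since the gene rows used hold mouse genes alone.

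Interneurons made up the largest named class of the sorted nuclei. GABAergic-like nuclei, the sum of the Pvalb-like, Sst-like and Lamp5-like clusters, were 275 of 835 or 32.9% (exact Clopper-Pearson 95% interval 29.8 to 36.2). Sst-like nuclei accounted for 17.1% (14.6 to 19.9), Pvalb-like nuclei for 12.1% (9.96 to 14.5) and Lamp5-like nuclei for 3.71% (2.54 to 5.23). Excitatory neurons were also present, with 17.4% glutamatergic-like nuclei (14.9 to 20.1), as were glia, with 8.62% astrocyte-like (6.81 to 10.7) and 5.63% oligodendrocyte-like nuclei (4.17 to 7.42). The nucleus filter lowers the oligodendrocyte-like share: when all nuclei were clustered together, 40 of the 69 left out were of this class. Another 0.838% were endothelial-like. No cluster met the markers of Vip or Sncg interneurons, although Vip reads were present in 7 of 31 Lamp5-like and 5 of 101 Pvalb-like nuclei. Clusters that met the markers of no class held 289 nuclei, and 214 of these, 25.6% of all nuclei (22.7 to 28.7), formed a single cluster without a cortical name. GABAergic-like does not cover every nucleus with transcripts of GABA synthesis, since 64.02% of the nuclei of this cluster had reads of Gad1 and 57.9% of Gad2. These intervals cover counting error only, and nuclei sorted together may share an animal.

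The share of GABAergic-like nuclei ranged from 16.3% in SYFP2-H2B-BORG to 59.5% in 3xsmOPT-SYFP2-H2B. The share of the large unnamed cluster ran from 0 to 48.4% over constructs, and that of astrocyte-like and oligodendrocyte-like nuclei together from 2.20% to 37.8%. These ranges describe the nuclei under each title, and no difference between constructs is drawn from them.

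**Figure D1:**
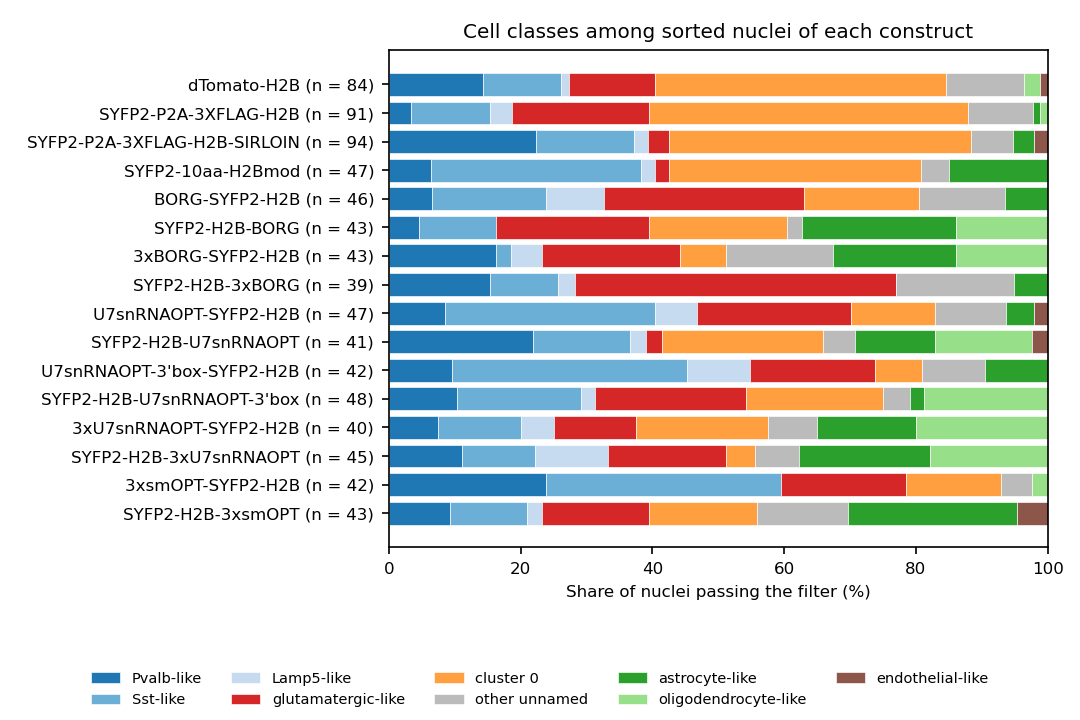
Share of nuclei in each class (percent of nuclei passing the filter, stacked bars) for each of the 16 constructs named in the titles, with the number of nuclei beside each name. Cluster 0 is the large unnamed cluster, and GABAergic-like nuclei (Pvalb-like, Sst-like and Lamp5-like together) span 16.3% to 59.5%.

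Placing the element before or after SYFP2-H2B left the cell classes without a difference that passed the test. With the element before the fusion, 40.3% ± 15.5 of nuclei were GABAergic-like (SD, n = 6 constructs), and with it after the fusion 28.6% ± 7.98; the share was higher after in 2 of 6 elements. The difference after against before was -11.8 percentage points, -5.01 without pool S40317, -23.8 without pool S40327 and -6.87 without the 3xsmOPT element. Sst-like nuclei, the somatostatin interneurons, were at 22.6% ± 13.9 before and 13.001% ± 3.18 after, higher after in 1 of 6. The sizes of these classes depend on the nucleus filter, without which Pvalb-like nuclei were 28.1% before and 21.7% after and Sst-like nuclei 7.64% and 2.64%. With the filter Pvalb-like shares were 12.02% and 12.1%, and glutamatergic-like shares 20.9% and 21.9% (28.2% and 57.3% over 5 elements without pool S40327). Astrocyte-like nuclei were 8.98% before and 14.7% after, oligodendrocyte-like nuclei 6.06% and 10.9%, Lamp5-like nuclei 5.71% and 3.42%, and nuclei of unnamed clusters 23.4% and 22.8%. In exact paired permutation tests over the 6 elements (two-sided, smallest possible p = 0.03125), p was 0.188 for GABAergic-like and 0.156 for Sst-like nuclei, both 0.75 after adjustment over the classes. With that adjustment a single class could not have passed even at the smallest possible p, so these tests cannot show that the shares are alike. The other exact permutation p-values ran from 0.375 for Lamp5-like and astrocyte-like nuclei to 1 for Pvalb-like nuclei, with 0.469 for oligodendrocyte-like, 0.844 for glutamatergic-like and 0.938 for unnamed nuclei. Library quality was also without a difference that passed, at a median of 248608 reads before and 254120 after (exact permutation p = 0.75) and 2895 and 2813 genes (exact permutation p = 0.688).

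**Figure D2:**
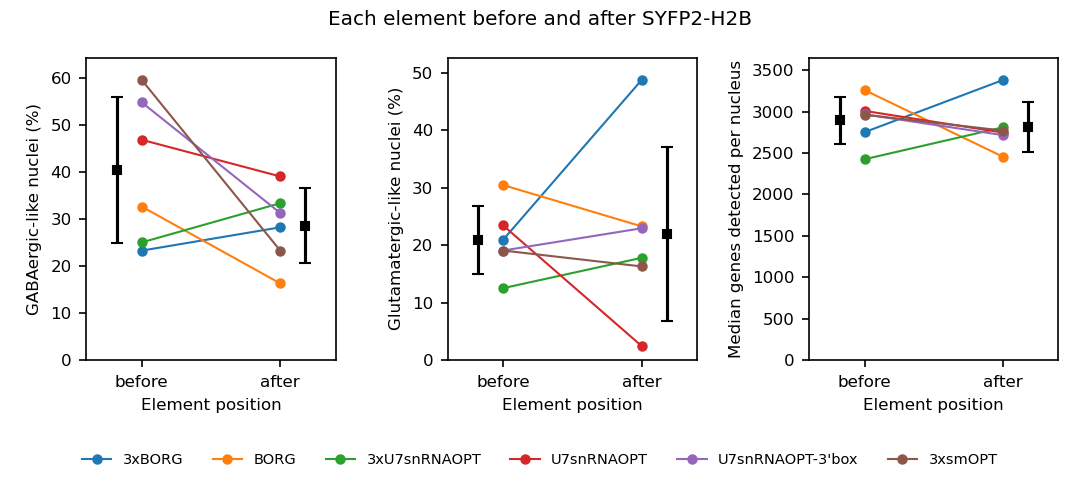
GABAergic-like share and glutamatergic-like share (percent of nuclei) and median genes detected per nucleus of the constructs with each element before and after SYFP2-H2B. Lines join the 2 constructs of an element, and black squares with bars are the mean ± SD over 6 elements; the GABAergic-like mean is 40.3% before and 28.6% after.

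No gene passed the test for element position either. The transcripts of Gad1 and Gad2, which encode the enzymes that make GABA, differed by log2 fold changes of -0.38 ± 0.41 (SE) and -0.13 ± 0.39 after against before, and Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, by 0.01 ± 0.44. Of the genes with the smallest p, Plxnb3, a plexin receptor for semaphorins on the X chromosome (mm10, 73757090 to 73772514), had 1990 reads after and 0 before, at least 651.7-fold higher in 4 of 6 elements. Ifnar2, a subunit of the type I interferon receptor (chromosome 16, 91372783 to 91405589), was at 2.20 ± 0.52 and higher after in 6 of 6. Afap1l2 had 1003 reads against 1, a ratio of 985.4 (counting interval 176.5 to 3.896e+04). Lower after were Frem1, a basement membrane protein, by at least 257.9-fold, the cationic amino acid transporter Slc7a3 at -1.34 ± 0.41 and Cntnap5a, a contactin-associated protein, at -0.92 ± 0.28, the last 2 in 6 of 6 elements. All of these had an adjusted p of 1. edgeR called 0 of 17063 genes, with 366 at an unadjusted p under 0.05, limma called 0, and DESeq2 called 157, of which 112 were higher after.

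Among the gene lists, interferon and antiviral response genes rose with the element after the fusion by camera (14 of 18 members above 0, median log2 fold change 0.75, adjusted p = 0.00148), and so did markers of glia and vascular cells (15 of 21, median 1.06, adjusted p = 0.0306). With an estimated correlation neither call held (adjusted p = 0.877 and adjusted p = 0.916 with an estimated correlation). None of their members was called over all genes, and 0 were called adjusted over the list alone. The class I histocompatibility gene H2-K1 stood at 2.92 ± 0.94, the interferon-induced Ifit3 at 6.29 ± 2.19, the microglial complement gene C1qa at least 64.51-fold higher and the collagen gene Col1a2 at least 51.42-fold higher. H2-K1 turned to -0.17 when nuclei needed at least 2000 genes and to -1.42 among GABAergic-like nuclei. The other lists did not pass: 3 of 12 GABAergic identity genes, 8 of 12 glutamatergic identity genes, 2 of 6 H2B histone genes, 16 of 27 other histone genes, 11 of 19 genes of Sm proteins and histone mRNA processing, 6 of 19 hnRNP genes, 2 of 10 nuclear long noncoding RNAs, 7 of 14 DNA damage and p53 targets, 10 of 16 heat shock genes, 13 of 18 immediate early genes, 10 of 12 mitochondrially encoded transcripts and 48 of 81 ribosomal protein genes were above 0.

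The family of the element was compared over the same 12 constructs, 4 with BORG and 8 with an Sm-site (OPT) element. Family is partly confounded with library pool, since pool S40317 supplied 71 of the 171 BORG nuclei and 35 of the 348 OPT nuclei. Hnrnpul2, an hnRNP gene for an RNA-binding nuclear protein (chromosome 19, 8820010 to 8834143), was at 81.1 ± 8.65 CPM (SD, n = 4) with BORG and 25.2 ± 10.1 (n = 8) with OPT, a log2 fold change of 1.72 ± 0.36 that had an adjusted p of 0.904. It was above the OPT mean in 4 of 4 BORG constructs and the synaptic vesicle GTPase Rab3c (0.99 ± 0.22) in 3 of 4. The selenoprotein gene Selenoo (-2.50 ± 0.60), Adck2 (-1.88 ± 0.47) and Anapc1, a subunit of the anaphase-promoting complex (-1.17 ± 0.29), were below the OPT mean in 4 of 4. edgeR called 0 of 15861 genes, with 873 at an unadjusted p under 0.05, limma 0 and DESeq2 58, of which 44 were lower with BORG.

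Ribosomal protein genes rose together with BORG by camera (78 of 81 above 0, median 0.55, adjusted p = 5.4e-16), as did mitochondrially encoded transcripts (12 of 12, median 1.99, adjusted p = 8.6e-14) and glutamatergic identity genes (11 of 12, median 0.55, adjusted p = 0.0169). None of these calls held when the correlation was estimated (adjusted p = 0.448, adjusted p = 0.448 and adjusted p = 0.458 with an estimated correlation). Rpl15, of the large ribosomal subunit, stood at 1.21 ± 0.38, Slc17a7 at 0.73 ± 0.41 and the layer marker Cux2 at -0.81 ± 0.66. Adjusted over the list alone, 1 gene was called among the GABAergic identity genes and 1 among the hnRNP genes, and 0 in any list over all genes. Without pool S40317, an alternative chosen after seeing the data, no list passed: 36 of 80 ribosomal protein genes (median -0.014), 0 of 8 mitochondrially encoded transcripts (median -0.49) and 9 of 12 glutamatergic identity genes (median 0.24) were above 0. The mitochondrial genes mt-Nd4 (2.07 ± 0.88) and mt-Nd5 (1.69 ± 0.71), which encode subunits of complex I, turned to -0.05 and -0.89 in that fit. Of the 87 nuclei with more than 0.3% mitochondrial reads, 58 belong to that pool.

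Copy number was compared in 4 pairs of constructs with 3 copies or 1 copy of BORG or U7snRNAOPT. Ly6a, a membrane protein of brain endothelial cells (chromosome 15, 74994877 to 74998031), had 0 reads with 3 copies and 4074 with 1, at least 1275-fold lower in 3 of 4 pairs, with an adjusted p of 0.323. Over all constructs only 7 kept nuclei were endothelial-like. Flt1, a receptor for vascular endothelial growth factor, had 1 read against 2251 (ratio 0.000473, counting interval 1.198e-05 to 0.00264), and the receptor tyrosine kinase gene Axl was at -7.71 ± 1.60, lower in 4 of 4. Markers of glia and vascular cells did not fall as a list (13 of 19 above 0, median 0.48, adjusted p = 0.795 by camera). Higher with 3 copies in 4 of 4 pairs were the antiviral adaptor Mavs (8.49 ± 1.75), the transporter Slco4a1 (1476 reads against 0, at least 524.2-fold) and Abhd4 (2.87 ± 0.63), which turned to -1.65 when nuclei needed at least 2000 genes. All had an adjusted p of 1 except Ly6a. edgeR called 0 of 16068 genes, with 341 at an unadjusted p under 0.05, limma 0 and DESeq2 116, 60 of them higher. Without a low-count filter edgeR called 1 gene, with nuclei of at least 2000 genes 7, and without the pair of BORG constructs after the fusion 2.

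By camera, immediate early genes rose with 3 copies (14 of 18 above 0, median 0.74, adjusted p = 0.0104), with Fos at 0.88 ± 0.40 and Btg2 at 1.48 ± 0.64. Mitochondrially encoded transcripts (12 of 12, median 0.97), ribosomal protein genes (65 of 81, median 0.29) and histone genes other than H2B (18 of 24, median 0.55) also rose, at adjusted p = 0.0104, adjusted p = 0.0104 and adjusted p = 0.024. Interferon genes fell (7 of 16 above 0, median -0.40, adjusted p = 0.0467). No call held when the correlation was estimated, with adjusted p = 0.386 for immediate early, histone and interferon genes and adjusted p = 0.762 for the others with an estimated correlation. Without pool S40317, chosen after seeing the data, no list passed, and the median of the ribosomal protein genes turned to -0.18. Members included mt-Co1 of complex IV (0.76 ± 0.55), mt-Nd5 (0.92 ± 0.77), Rps27a (0.98 ± 0.45) and Rps24 (-1.002 ± 0.49) of the small ribosomal subunit, the variant histone H2afy2 (1.103 ± 0.75), Hist1h2ac (at least 95.9-fold higher), Ifitm3 (-8.03 ± 2.13) and H2-D1 (-0.80 ± 0.40). Over all genes 0 members were called, and adjusted over the list alone 2 of the glia and vascular list.

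The suffix BC in the construct names was compared within pool S40325, over the 3 constructs without it and the 7 with it that had at least 8 nuclei there. Those without it are dTomato-H2B and both P2A constructs, whose reporters occur in none of the 7, so the suffix is confounded with the form of the reporter. Zinc finger gene Zfp111 had 1 read in the BC constructs and 585 in the others, a ratio of 0.00414 (counting interval 0.000105 to 0.0231), Rnf17 3 against 1021 (0.00711, interval 0.00146 to 0.0208) and Slain1os 1 against 635 (0.00381, interval 9.634e-05 to 0.0213). Ppp1r3g, a regulator of glycogen synthesis, was at least 1212-fold higher with BC, the kinase gene Ikbke at least 41.95-fold and Prickle4 at least 31.46-fold, each in 3 of 7 constructs and at an adjusted p of 1. Immediate early genes fell with BC by camera (3 of 17 above 0, median -0.72, adjusted p = 0.00683; adjusted p = 0.811 with an estimated correlation), with Fosb at -4.03 ± 2.02 and Junb at -1.12 ± 0.80. edgeR called 0 of 14077 genes, with 115 at an unadjusted p under 0.05, limma 0 and DESeq2 3, and 0 list members were called over all genes or adjusted over the list alone. The median of all genes was -0.01 here and 0.19 with RLE scaling or 0.15 with that of DESeq2, and with RLE the medians of the glutamatergic identity, hnRNP, nuclear long noncoding RNA, ribosomal and Sm lists changed sign, none of which had passed; that of the immediate early genes stayed negative at -0.46. With all pools in the comparison Zfp111 was at 0.18, and among GABAergic-like nuclei Junb was at 0.56.

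Cell classes were spread unevenly over the library pools. The pools also hold different constructs: dTomato-H2B, SYFP2-10aa-H2Bmod and both P2A constructs together gave 0 nuclei to pool S40317, 276 to pool S40325 and 40 to pool S40327. The shares below therefore follow construct as well as pool. In pool S40317, 58.5% of 106 nuclei were glutamatergic-like, against 9.95% of 362 nuclei in pool S40327 and 12.8% of 367 in pool S40325. GABAergic-like nuclei were 22.6%, 37.02% and 31.9% in that order. The first of these depends on the naming of clusters, since an unnamed cluster of 14 nuclei, all of pool S40317, had 6 of 7 GABAergic and 6 of 8 Pvalb markers raised, though none among its leading genes. Oligodendrocyte-like nuclei were 0 of 106 in pool S40317 (which allows up to 2.83%), 11.6% in pool S40327 and 1.36% in pool S40325, and astrocyte-like nuclei 5.66%, 14.9% and 3.27%. The large unnamed cluster was absent from the 106 nuclei of pool S40317 and made up 18.5% of pool S40327 and 40.1% of pool S40325. Mitochondrially encoded transcripts took a median of 1.27% of reads in pool S40317, 0.0009% in pool S40325 and 0.0005% in pool S40327, and 58, 14 and 15 nuclei exceeded 0.3%. The first median describes neither part of its pool, as those 58 nuclei lay between 0.835% and 9.87% and the other 48 at 0.0884% or less. Median genes detected were 3811, 2747 and 2716 at medians of 274035, 272433 and 244318 reads.

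**Figure D3:**
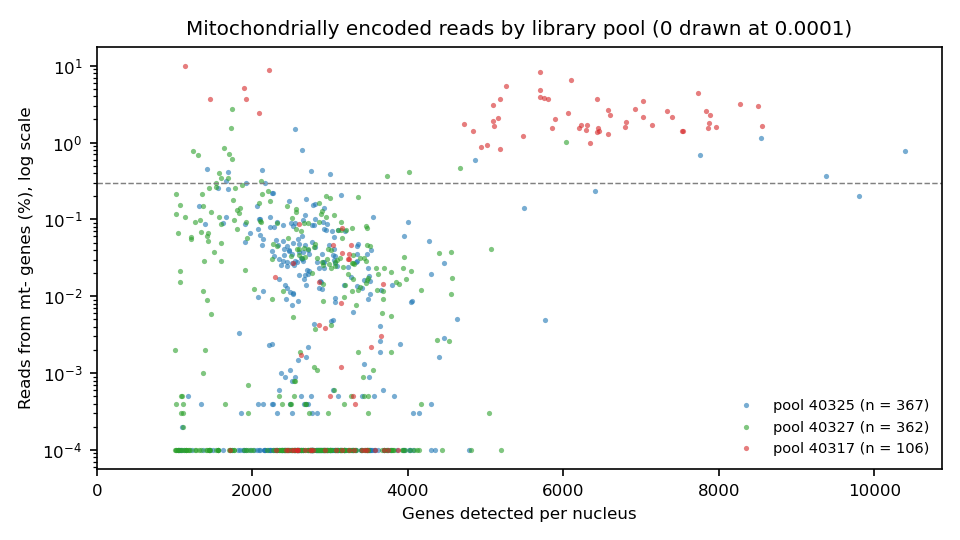
Genes detected against the percent of reads from mitochondrially encoded transcripts (log axis, 0 drawn at 0.0001) for each nucleus passing the filter and coloured by library pool. The dashed line marks 0.3%, which 58 of 106 nuclei exceed in pool S40317, 14 of 367 in pool S40325 and 15 of 362 in pool S40327.

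Within 8 constructs with at least 5 nuclei in both, genes of excitatory neurons were higher in pool S40317 than in pool S40327. Single genes of oligodendrocytes were lower, though the list of glia and vascular markers lost its call with an estimated correlation. Slc17a7 (chromosome 7, 45163949 to 45176142) was at 333 ± 141 CPM against 77.4 ± 55.9 (SD, n = 8), a log2 fold change of 2.04 ± 0.40 seen in 8 of 8 constructs (adjusted p = 0.0318). Among the largest called increases were the neurotrophin gene Bdnf (chromosome 2, 109674700 to 109727007; 8.92 ± 1.84, 8 of 8, adjusted p = 0.0426), the early response transcription factor Nr4a2 (7.87 ± 1.37, 7 of 8) and the neuropeptide gene Adcyap1 (9.08 ± 1.76, 7 of 8). Also higher were the 14-3-3 gene Ywhag (2.60 ± 0.40), the small GTPase Arf3 (2.65 ± 0.49), beta-synuclein Sncb (3.11 ± 0.55), the calcium sensor Vsnl1 (3.30 ± 0.66), Ube2ql1 (3.21 ± 0.54), Mgst3 (2.58 ± 0.52) and Basp1 (2.53 ± 0.52, but -0.60 among GABAergic-like nuclei alone), in 6 to 8 of 8 constructs. The myelin gene Mag (chromosome 7, 30899176 to 30914873) had 0 reads in pool S40317 and 20169 in pool S40327, at least 4210-fold lower in 7 of 8 constructs (adjusted p = 0.000353). The myelin genes Mal and Opalin were at least 5330-fold and 2481-fold lower in 4 of 8, the lineage factor Olig1 at least 1200-fold in 5 of 8, Tmem63a and Gjc3 at least 1190-fold and 1089-fold in 3 of 8, and the iron carrier gene Trf and the myelin gene Mbp were at -11.42 ± 1.396 and -4.41 ± 0.72. The hedgehog-binding Hhip was at least 1107-fold lower in 7 of 8 and the substance P receptor Tacr1 at least 523.1-fold lower in 8 of 8. Malat1, a noncoding RNA that stays in the nucleus, fell by 1.36 on the log2 scale with an SE of 0.22, from 181914 to 89442 CPM, in 8 of 8 (adjusted p = 0.0115).

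edgeR called 57 of 15467 genes between these pools, 24 higher and 33 lower in pool S40317, with 1540 at an unadjusted p under 0.05, DESeq2 called 1389 and limma 3417, and among GABAergic-like nuclei alone, with 4 summed libraries, edgeR called 1. In counts simulated for this comparison 12 of 14617 unchanged genes were called. By camera the glutamatergic identity genes (11 of 12 above 0, median 2.08, adjusted p = 1.7e-08) and immediate early genes (15 of 18, median 1.22, adjusted p = 1.3e-06) rose, and both calls held, at adjusted p = 0.0213 with an estimated correlation. Of these lists 1 member each was called over all genes and 5 and 4 adjusted over the list alone; Neurod6, a transcription factor of excitatory neurons, was at 5.25 ± 1.12 (adjusted p = 0.0511) and Nr4a3 at 5.91 ± 1.56. Mitochondrially encoded transcripts (12 of 12, median 4.50, adjusted p = 2.1e-08), ribosomal protein genes (74 of 81, median 1.15, adjusted p = 7.1e-13) and heat shock genes (12 of 16, median 0.61, adjusted p = 0.0159) rose and glia and vascular markers fell (4 of 15 above 0, median -3.44, adjusted p = 3.1e-05). These calls were lost at adjusted p = 0.359, adjusted p = 0.359, adjusted p = 0.393 and adjusted p = 0.345 with an estimated correlation. With genes at 0 reads set to their bound the medians of these lists did not move, but with DESeq2 that of the glia and vascular markers was -1.47. Among them 0, 0, 0 and 3 members were called over all genes and 7, 1, 1 and 5 adjusted over the list alone, with mt-Nd1 at 5.005 ± 1.46, mt-Nd3 at 7.10 ± 1.81, Rpl38 at 2.57 ± 0.58, and the chaperones Hsp90aa1 at 1.17 ± 0.31 and Hspe1 at 1.41 ± 0.46. Of the nuclear long noncoding RNAs 1 was called and 2 adjusted over the list alone, and the list did not pass (2 of 10 above 0, adjusted p = 0.205). Without SYFP2-H2B-BORG edgeR called 10 genes, without 3xBORG-SYFP2-H2B 14, without SYFP2-H2B-3xU7snRNAOPT 18, without U7snRNAOPT-SYFP2-H2B 33, and without either 3xsmOPT construct 124. Mag, Mal, Hhip, Opalin, Tacr1, Trf and Ywhag were called with each construct left out, the other genes named here not, and Mag, Mal and Trf lost the call when nuclei needed at least 2000 genes.

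Pools S40325 and S40327 were compared within 10 constructs. Vitronectin, Vtn, a gene of mural cells (chromosome 11, 78499091 to 78502324), was at 9.91 ± 1.70 in pool S40325, higher in 4 of 10 constructs, with an adjusted p of 0.37. Nrros, a microglial gene, stood at 7.34 ± 2.10, Trf at 6.27 ± 1.69 and Flt1 at 7.36 ± 2.66, and the opioid peptide gene Pdyn at -6.28 ± 1.71, Gdf10 at -6.05 ± 1.64 and the kinase gene Cdk11b at -1.20 ± 0.33, the last in 10 of 10. GABAergic identity genes fell by camera (0 of 12 above 0, median -1.12, adjusted p = 2.5e-05), with Maf at -1.95 ± 0.97 and Dlx6os1 at -1.53 ± 0.82, and glia and vascular markers rose (15 of 21, median 0.84, adjusted p = 0.0215). Both had adjusted p = 0.994 with an estimated correlation, 0 members were called over all genes, and adjusted over the list alone 1 glia or vascular gene was. edgeR called 0 of 16477 genes, with 323 at an unadjusted p under 0.05, limma 0 and DESeq2 260. Without a low-count filter edgeR called 9 genes, with nuclei of at least 2000 genes 1, and without dTomato-H2B 1.

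Pvalb-like and Sst-like nuclei were compared in 6 constructs with at least 5 nuclei of both, over ion channel, receptor and cadherin genes that had been kept out of the clustering. Among the genes called higher in Pvalb-like nuclei, the GABA receptor subunits Gabrd (412 ± 151 against 82.8 ± 96.8 CPM, SD, n = 6) and Gabrg3 rose by 3.597 ± 0.76 in 5 of 6 constructs (adjusted p = 0.00424) and by 2.56 ± 0.62 in 6 of 6. The fast potassium channel gene Kcnc1 (chromosome 7, 46396497 to 46438704) was at 1092 ± 354 against 398 ± 153 CPM, 1.48 ± 0.27 higher in 6 of 6 (adjusted p = 0.000489). In Sst-like nuclei the glutamate receptor subunit Grin3a (chromosome 4, 49661611 to 49845744) had 3854 reads against 0, so that it was at least 1427-fold lower in Pvalb-like nuclei in 6 of 6 (adjusted p = 1.3e-12). The calcium channel genes Cacna2d3 (chromosome 14, 28904943 to 29721864; -9.14 ± 1.09, adjusted p = 2.9e-09) and Cacna1e (-4.83 ± 0.97) and the cell adhesion genes Pcdh8 (-8.89 ± 2.17) and Cdh4 (-7.17 ± 1.84) were also lower in Pvalb-like nuclei, in 5 or 6 of 6 constructs. Without a nucleus filter, which changes the clusters, Pcdh8 and Cdh4 turned to 9.27 and 2.94.

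edgeR called 9 of 175 of these genes, 4 higher and 5 lower in Pvalb-like nuclei, with 33 at an unadjusted p under 0.05. Glutamate receptors (5 of 21 above 0, median -0.81, adjusted p = 9.5e-05), cadherins and protocadherins (6 of 23, median -0.82, adjusted p = 0.00275) and calcium channels (5 of 20, median -0.89, adjusted p = 0.00358) fell by camera, though not with the correlation estimated (adjusted p = 0.174, adjusted p = 0.312 and adjusted p = 0.127 with an estimated correlation). Over all genes 1, 2 and 2 members of these lists were called, and 2, 7 and 2 adjusted over the list alone. GABA receptors had 3 called members (4 adjusted over the list alone), potassium channels 1 (5 adjusted over the list alone), and the monoamine, acetylcholine and opioid receptors and the sodium and HCN channels 0; these lists did not pass as sets. Pcdh11x (-2.81 ± 0.75, adjusted p = 0.0501; 2.47 without a nucleus filter), Cdh13 (-1.91 ± 0.52), Kcnh7 (1.64 ± 0.49), Kcnab3 (2.48 ± 0.73) and Kcnip2 (4.71 ± 1.44) did not pass. Leaving out 1 construct at a time gave 6 to 8 calls; Cdh4 lost its call in every such fit, Pcdh8 in all but the fit without SYFP2-H2B-3xU7snRNAOPT, and Gabrd and Gabrg3 each in 3. A second Sst-like cluster of 49 nuclei carries the markers Nos1 and Chodl, and without it, an alternative chosen after seeing the data, 3 genes were called.

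GABAergic-like and glutamatergic-like nuclei were compared over the same kinds of genes in 13 constructs. GABAergic-like nuclei had more of the calcium-gated potassium channel subunit Kcnmb2 (chromosome 3, 31902507 to 32200180; 78.2 ± 44.7 against 1.97 ± 7.04 CPM, SD, n = 13), by 9.56 ± 1.095 (adjusted p = 2.4e-07), of the channel-interacting protein Kcnip1 (chromosome 11, 33629339 to 33993152; 7.52 ± 0.86, adjusted p = 2.2e-07) and of Kcnc1 (2.81 ± 0.26, adjusted p = 3.0e-09), each in 13 of 13 constructs. Kcns3 (9.21 ± 1.103), Kcna3 (8.07 ± 1.66), the receptor genes Gabrg1 (8.19 ± 1.64), Grin3a (6.64 ± 1.35), Grik1 (2.80 ± 0.47), Gabrg3 (1.93 ± 0.45), Adra1a (6.10 ± 1.29), Htr2c (7.004 ± 2.06) and Drd1 (5.75 ± 1.19), the calcium channel gene Cacna2d2 (6.19 ± 1.24) and the sodium channel gene Scn9a (4.28 ± 0.78) were higher as well, in 8 to 13 constructs. Pcdh18 had 1305 reads against 2, a ratio of 435.1 (counting interval 120.2 to 3596). Glutamatergic-like nuclei had more of the potassium channel genes Kcnh4 (-9.22 ± 1.399, adjusted p = 3.0e-05), Kcnv1 (-6.97 ± 1.002), Kcnh3 (-6.26 ± 1.32), Kcng1 (-5.66 ± 1.65), Kcnj2 (-5.55 ± 1.64), Kcnip3 (-5.02 ± 0.94), Kcnk4 (-4.83 ± 1.25) and Kcnh1 (-3.17 ± 0.95). The glutamate receptors Grm8 (-7.81 ± 1.54) and Grin2b (-0.93 ± 0.15), the adhesion genes Cdh6 (-6.34 ± 1.001) and Pcdh9 (-1.25 ± 0.22), Cacna2d1 (-2.31 ± 0.41) and the sodium channel gene Scn2a (-0.77 ± 0.22) lay the same way, in 11 to 13 of 13.

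edgeR called 50 of these 208 genes, 23 higher and 27 lower in GABAergic-like nuclei, with 86 at an unadjusted p under 0.05. Potassium channels fell as a set by camera (26 of 70 above 0, median -0.85, adjusted p = 0.0449; adjusted p = 0.462 with an estimated correlation), with 7 members called higher and 14 lower, and 25 adjusted over the list alone. The other lists did not pass as sets: cadherins had 3 members higher and 5 lower (11 adjusted over the list alone), calcium channels 1 and 3 (4), GABA receptors 3 and 1 (4), glutamate receptors 5 and 3 (12), monoamine, acetylcholine and opioid receptors 3 and 0 (3), and sodium and HCN channels 1 and 1 (4). With at least 10 nuclei of both classes 26 genes were called, and without pool S40317, an alternative chosen after seeing the data, 24, of which 21 were among the 50. Htr2c, Kcng1, Kcnh1, Kcnj2 and Scn2a lost the call when single constructs were left out.

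**Figure D4:**
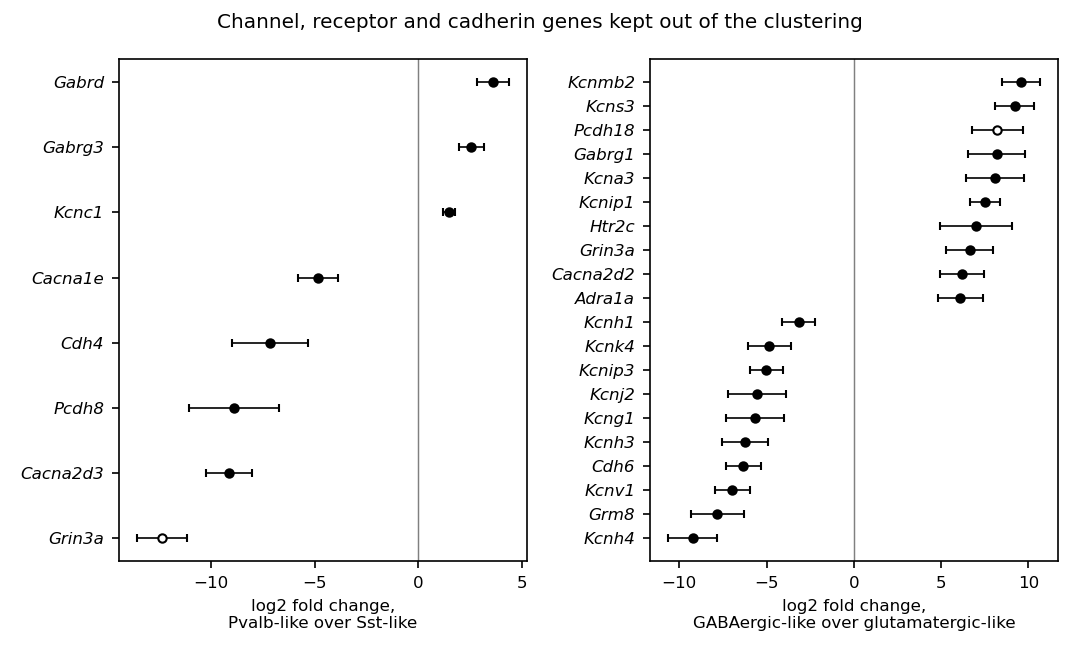
Log2 fold change ± SE of genes kept out of the clustering, Pvalb-like against Sst-like nuclei (left, n = 6 constructs) and GABAergic-like against glutamatergic-like nuclei (right, n = 13). Open circles mark genes with 3 or fewer reads on 1 side, whose fitted value is no bound (Grin3a on the left, Pcdh18 on the right).

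Single constructs were set side by side without a test, since each is 1 sample. With SIRLOIN after SYFP2-P2A-3XFLAG-H2B, 39.4% of 94 nuclei were GABAergic-like (Clopper-Pearson 29.4 to 50.0) and 3.19% glutamatergic-like, against 18.7% (11.3 to 28.2) and 20.9% of 91 nuclei without it (intervals that take nuclei as independent and are too narrow where nuclei sorted together resemble each other), while the large unnamed cluster held 45.7% and 48.4%. Gad1 was at 509 and 322 CPM, Gad2 at 235 and 227, Slc17a7 at 28.1 and 120, Pvalb at 141 and 43.9 and the neuropeptide gene Sst at 629 and 1787. Markers of other cells differed too, but rest on very few nuclei. Mog of oligodendrocytes was at 0.111 and 159 CPM, with reads in 1.06% and 2.20% of nuclei. Rgs5 of mural cells was at 59.1 CPM with SIRLOIN, from 3.19% of nuclei, and at 0 reads without it. Of 4752 genes compared, 184 were at least 2-fold higher with SIRLOIN and 163 at 0.5 or less. The largest ratio was that of the mitotic kinase gene Nek7 (chromosome 1, 138482875 to 138620141), at 59.8 CPM (Poisson interval 56.9 to 62.8) against 6.29 (5.36 to 7.34). The sialomucin gene Cd164 followed at a ratio of 8.63, the integrin gene Itga1 at 6.86, Trnp1 at 5.85 and the Golgi gene Cog8 at 4.33, and in the other direction Cdk14 at 6.48, Kcnh3 at 6.27, Ubxn11 at 6.03, Tnrc18 at 4.72 and Pex5l at 4.62.

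For dTomato-H2B, 27.4% of 84 nuclei were GABAergic-like (18.2 to 38.2), 13.1% glutamatergic-like and 44.05% in the large unnamed cluster. Gad1 was at 455 CPM and Slc17a7 at 79.2, against 322 and 120 in the P2A construct. Of 4772 genes, 181 were at least 2-fold higher with dTomato-H2B and 125 at 0.5 or less. Rxylt1, a glycosyltransferase gene, led at a ratio of 7.32, before Trnp1 (6.52), Plekhm3 (5.40), Ccdc6 (5.14) and Dzip1l (4.88). The chromatin reader gene Brpf3 (chromosome 17, 28801090 to 28839949) was at 1.62 CPM (Poisson interval 1.14 to 2.23) against 20.2 (18.5 to 22.01), a ratio of 12.5 the other way, followed by Tarsl2 (7.72), the signalling inhibitor Spry2 (6.404), Galk2 (5.70) and Spats2 (5.63). These intervals cover counting error within the summed reads, which few nuclei can dominate.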

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

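None of the tests here was chosen after the result was seen. Among constructs with the element after SYFP2-H2B, the share of Lamp5-like nuclei was 11.1% with 3xU7snRNAOPT, far from the next construct at 2.56%: the gap is 0.769 of the whole range, beyond the 95% limit for 6 samples. This was 1 of 40 groups examined for a sample far from the others, and chance flags about 1 in 20.

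Between elements in 3 copies and in 1 copy, the change from before to after SYFP2-H2B went in opposite directions, for the BORG and U7snRNAOPT elements alike, in 4 measures. The share of GABAergic-like nuclei changed by 6.64 percentage points with 3 copies and by -12.1 with 1, that of glutamatergic-like nuclei by 16.5 and -14.1, that of oligodendrocyte-like nuclei by -8.09 and 14.3, and the median of genes detected by 508 and -533.8. The other measures examined for element position did not show this pattern. With 2 elements on each side this difference was not tested. Pool S40317 gave 16 nuclei with 3xBORG before and 24 after, and 23 and 8 with BORG. It gave 11 nuclei with 3xU7snRNAOPT after and none before, and 8 with U7snRNAOPT before and none after. The nuclei of this pool thus changed in the same directions, so copy number and pool cannot be told apart here. The elements without a partner in the other copy number do not follow it throughout: 3xsmOPT changed by -36.3 points in GABAergic-like nuclei, -2.77 in glutamatergic-like nuclei and -191.5 genes, and U7snRNAOPT-3'box by 3.87 points in glutamatergic-like nuclei.

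The 69 nuclei left out by the nucleus filter were clustered together with all others to see what they hold. Oligodendrocyte-like nuclei were 57.97% of them (Clopper-Pearson 45.5 to 69.8) and astrocyte-like nuclei 11.6% (5.14 to 21.6). Both are above the 4.35% that a count of 0 allows, which shows only that such nuclei are there; against the kept nuclei only the oligodendrocyte-like share is higher beyond its interval, as that of astrocyte-like nuclei covers their 8.62% among the kept. Oligodendrocyte-like and astrocyte-like nuclei that passed the filter had medians of 1123 and 1564 genes, and the filter asks for 1000.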

How the results depend on the processing

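The tests without pool S40317, without the second Sst-like cluster, without the mitochondrial-led glutamatergic-like cluster and of the large unnamed cluster were chosen after seeing the data. By the numbers in the titles no paired analysis was possible because they only number the nuclei of a construct and name no animal; pairs by element or construct are in the fits already. Of 87 genes named as called, 1410 of 1617 values under the alternatives kept direction and call, 204 lost the call and 3 changed direction. Of 68 named as not called, 975 of 1079 stayed so, 79 passed and 25 changed direction. RLE scaling changed no count of calls by more than 1.5 times.

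DESeq2 called more genes in every comparison: 157 for element position, 58 for family, 116 for copy number, 3 for the suffix BC, 260 for pool S40325, 1389 for pool S40317, 31 between Pvalb-like and Sst-like, 77 between GABAergic-like and glutamatergic-like nuclei, and 116 for the large unnamed cluster. Limma on means over nuclei called 3417 genes for pool S40317 and 94 between GABAergic-like and glutamatergic-like nuclei. Without a low-count filter edgeR called 1 gene for copy number, 9 for pool S40325 and 154 for pool S40317, and with at least 2000 genes per nucleus 7, 1 and 94. Among GABAergic-like nuclei alone pool S40317 had 1 call, with fewer nuclei summed. Pvalb-like against Sst-like gave 19 calls without a nucleus filter, 1 without a block and 3 without the second Sst-like cluster, and GABAergic-like against glutamatergic-like 26 with at least 10 nuclei per sum and 24 without pool S40317. Leaving out single constructs or pairs gave 0 to 2 calls for copy number, 0 to 1 for pool S40325 and 10 to 124 for pool S40317. The cause of these changes in the counts was not tested, the number of nuclei used included.

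With an estimated correlation camera called 0 lists for element position, family, copy number, the suffix BC, pool S40325, Pvalb-like against Sst-like, GABAergic-like against glutamatergic-like and the large unnamed cluster, and 2 for pool S40317; the estimate allows for members that vary together. Without pool S40317, chosen after seeing the data, camera called 0 lists for family and 0 for copy number, where the calls had been 3 and 5, and 2 for element position as before.

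Directions that reversed were these. For element position, Gad2 was at 0.058 with at least 2000 genes, at 0.11 without pool S40317 and at -0.37 to 0.22 with single elements left out. H2-K1 was at -0.17 with at least 2000 genes and at -1.42 among GABAergic-like nuclei. Slc17a7 was at -0.038 with pool as a term, -0.92 among GABAergic-like nuclei, -0.35 without pool S40317 and -0.25 to 0.44 with single elements left out. For family, mt-Nd5 was at -0.49 with pool as a term and -0.89 without pool S40317, mt-Nd4 at -0.053 without pool S40317 and Slc17a7 at -8.95 among GABAergic-like nuclei. For copy number, Abhd4 was at -1.65 with at least 2000 genes, H2-D1 at 0.074 in limma and 0.25 among GABAergic-like nuclei, Btg2 at -6.29 and Rps27a at -0.45 among the same nuclei. For the suffix BC, Junb was at 0.56 among GABAergic-like nuclei and Zfp111 at 0.18 with all pools. Basp1 was at -0.60 for pool S40317 among GABAergic-like nuclei. Without a nucleus filter, Cdh4 was at 2.94, Pcdh11x at 2.47 and Pcdh8 at 9.27 between Pvalb-like and Sst-like nuclei. The cause was not tested.

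Differences of class shares after against before, in percentage points, passed no test under the alternatives run, and some changed sign. With a single element left out, or without pool S40327, the paired test cannot give a p under 0.05, so those alternatives could not pass. Pvalb-like nuclei were at -6.46 without a nucleus filter (where Sst-like nuclei were at -5.0), -2.76 without pool S40325, -1.11 at resolution 2 and -2.55 to 3.04 with single elements left out. Glutamatergic-like nuclei were at -2.59 without pool S40317, -4.96 without pool S40325, 29.1 without pool S40327 and -4.35 to 5.40 with single elements left out, and astrocyte-like nuclei at -1.87 without pool S40327. Unnamed nuclei were at 3.40 without a nucleus filter, 0.931 without pool S40325, 2.86 at resolution 0.5 and -2.94 to 2.58 with single elements left out. Median reads differed by -25804 without pool S40327 and by -6984 to 13954 with single elements left out, and median genes by 353.6 without pool S40327 and by -224.9 to 62.2 with single elements left out. The cause was not tested.

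Between single constructs, 17 genes kept their value and 3 moved when only pool S40325 was used, and as many when CPM were averaged over nuclei. Vip-like against Lamp5-like and medial against caudal interneurons were not run under any alternative, nor was Pvalb-like against Sst-like with at least 10 nuclei per sum, as too few constructs held enough nuclei.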

Other observations

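The tests that compare the large unnamed cluster with GABAergic-like nuclei and the tests of read depth and cell class makeup for pool S40317 were chosen only after the result was seen. The large unnamed cluster differed from GABAergic-like nuclei in single receptor and channel genes, in both directions. Drd2, a dopamine receptor gene (chromosome 9, 49340627 to 49408177), had 6607 reads in it against 3 in GABAergic-like nuclei of the same 12 constructs. That is a ratio of 2244 (counting interval 767.5 to 10884), higher in 11 of 12 (adjusted p = 4.4e-08). Another dopamine receptor gene, Drd1, named here outside the naming rule, was also called higher by edgeR. It was at 507 against 52.8 CPM (3.30 ± 0.62, adjusted p = 0.000533), so the cluster is not marked by Drd2 alone. The serotonin receptor Htr1b (9.52 log2 units higher), the adrenergic receptor Adra2c (9.28), the sodium channel subunit Scn4b (9.22 ± 1.23, SE), the potassium channel genes Kcnh4 (10.18 ± 1.14) and Kcng1 (8.48) and the glutamate receptor Grm5 (1.88 ± 0.20; 1466 ± 362 against 439 ± 143 CPM, SD, n = 12) rose as well. Lower were Grin3a by at least 2145-fold, Kcns3 by at least 1892-fold, Kcnmb2 by at least 1465-fold, and Grik1 (-11.68 ± 0.81), Kcnip1 (-11.36) and Kcnc1 (-3.80 ± 0.40). edgeR called 75 of 211 held-out genes, 35 higher and 40 lower. Calcium channels rose by camera (13 of 22 above 0, median 0.69, adjusted p = 0.0242; adjusted p = 0.0575 with an estimated correlation), with 5 members called higher and 1 lower and 9 adjusted over the list alone. The other lists, receptors among them, did not pass as sets. The median of all genes was -0.70, and -0.49 with DESeq2.

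Striatal genes in nuclei labelled visual cortex form the first pattern weighed. A list of 10 striatal genes written down from their known expression had a median fold of 15.065 in this cluster over Pvalb-like and glutamatergic-like nuclei. The transcription factors Meis2 and Foxp1 were at 648 against 44.97 CPM and at a fold of 4.63. Nuclei of striatal projection neurons in the set would give such values. The list leaves out the leading genes of the cluster, so it was drawn up after these were seen. Its genes were not kept out of the clustering, so the fold is not independent evidence. Cortical nuclei with striatal RNA added, from free RNA or doublets, are excluded: the median level of glutamatergic markers in the cluster was 0.0109 of that in glutamatergic-like nuclei, with Slc17a7 at 3.59 against 591 CPM. Of these 8 markers Camk2a (0.522), Nrgn (0.386) and Sv2b (0.23), named here after their values were seen, lay above 0.2, and the others at 0.016 or below. The protocol text names striatum among the regions sorted, and a tissue label that is wrong for these nuclei is consistent with the values, though no label can settle it.

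Mitochondrial transcripts in pool S40317 form the second pattern. Makeup of cell classes is excluded as the whole cause: in the astrocyte-like cluster the median mitochondrial percentage of 6 nuclei of this pool was 73.89 times that of the other pools, and in the Lamp5-like cluster that of 8 nuclei 949.63 times, each of these nuclei above every nucleus of the other pools in its cluster. For glutamatergic-like nuclei makeup stays open. Their ratio was 47.5, with the other pools set to the floor of 3 counts, but it rests on a cluster of 30 nuclei found in this pool alone (median 1.7052%), and in the cluster that the pools share the medians were 0.0002% and 0.0006%. Pvalb-like and Sst-like nuclei of this pool had medians of 0. These classes leave out the unnamed cluster of 14 nuclei with raised GABAergic and Pvalb markers, all of this pool. Its median was 2.0996% and its lowest value 0.9299%. The pool is split, with 50 of its 64 nuclei above the median reads of pool S40327 over 0.3% and 8 of its 42 others, so a median over it covers unlike nuclei. Read depth is excluded among nuclei with more reads than the median nucleus of pool S40327, where the median of 1.6197% was 1546.6 times the floor of 3 counts in pool S40327, whose own median of 0.0007% lies below it. Among nuclei of matched lower reads the medians leave read depth open, as both (0.0014% and 0.0005%) lie below the floor and the ratio to it was 0.97. Of those nuclei 8 of 42 in pool S40317 were over 0.3%, against 6 of 181 in pool S40327 and 3 of 114 in pool S40325. Their median reads were 205244, 201034 and 218971.5. These counts, which were not tested, argue against read depth for the nuclei over 0.3%. Over all nuclei median reads of pools S40317 and S40327 differed 1.122 times, which does not decide. Pool S40325 argues against read depth there. Its median of 272433 reads is near the 274035 of pool S40317, yet 14 of its 367 nuclei were over 0.3%, against 58 of 106. Cytoplasmic RNA in these libraries also stays open: ribosomal protein genes were 1.147 log2 units higher at the median and nuclear long noncoding RNAs 0.41 lower, and no biological explanation was tested.

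Other splits of the same summed libraries were fitted to see whether a count of calls could come from any division of them. Where edgeR called 0 genes every split gives as many by definition, so the count says nothing about chance: for element position 100 of 100 splits did, the highest with 5 calls, and with positions exchanged within elements 32 of 32, the highest with 0; for family 100 of 100 (highest 2), for copy number 32 of 32 (highest 2), for the suffix BC 100 of 100 (highest 5) and for pool S40325 60 of 60 (highest 14). Why some of these splits call genes was not tested. For pool S40317 with 57 calls, 3 of 100 splits gave as many, the real one among them and others with 70 and 63. That share is under 5%, but these other splits called more genes, and 100 of 128 possible exchanges were run. Chance is therefore not excluded for this count. Between Pvalb-like and Sst-like nuclei the real division gave the most calls (9 calls, 1 of 32 splits, highest other 3). The same held between GABAergic-like and glutamatergic-like nuclei (50, 1 of 36, highest other 11) and for the large unnamed cluster (75, 1 of 32, highest other 19). These sides are clusters formed from the same nuclei, so exchanging them within constructs mixes groups that were built to differ. For the classes the splits therefore cannot exclude chance.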
